A study of Drosophila melanogaster with 32 samples.

How the data were processed

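DamID-seq was run on genomic DNA of neurons of the Drosophila melanogaster larval central nervous system, per the labels. In DamID a protein is fused to a bacterial adenine methylase (Dam), which methylates GATC sequences near the DNA the protein contacts, and the methylated fragments are cut out with DpnI, amplified and sequenced. A library of Dam alone serves as the control. Animals were raised at 18 degrees and moved to 29 degrees 24 h before the DNA was taken, per the labels. The series held 32 samples in 18 groups, and 29 samples with a file were used here. Samples of Dam alone in female and in male neurons, and 1 of the samples of Dam alone in Polr3E RNAi, were not used here.

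Reads were aligned with Bowtie2 to BDGP6 according to the submitters' processing notes, and the versions are not given in the sources used here. The deposited values of the fusion libraries were log2 ratios of fusion over Dam alone, 1 value per GATC fragment, as the feature column of most files states. The deposited U2af50 file gave log2 values in bins of 75 bp and its ratio was taken from the pattern of its values. The deposited values of Dam alone in Polr3E RNAi and of Dam alone without RNAi were mean coverage per fragment in RPM, whose sum over all fragments was 1e+06. The deposited signal of Dam alone in Polr3A RNAi was labelled as RPM by the authors, but summed to 1.83e+07 and 2.27e+07, so it was read as unscaled mean coverage and was scaled to a sum of 1e+06 here. Which Dam-alone library served as the denominator of each ratio, and how the ratios were centred, are not given in the sources used here. The file headers call Polr3E by its synonym SIN. The labels U1, Sxl_RNA and Sxl_GS were kept as given. The pair of Sxl_RNA files held equal values on all 383682 fragments, so they were used as 1 library. In the second Dam-alone library, 18 lines held a value without coordinates and were left out. The depth of the ratio and RPM libraries is not given in their files, so no counting error could be attached to their values. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

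Genes were taken from an annotation of Release 6, the same release as BDGP6. The table of genes gave no strand, so a transcription start could not be placed, and each gene was read in windows of 1000 bp centred on both of its annotated ends, called here the low end and the high end by coordinate. Genes shorter than 1000 bp had 1 window at their middle. This departs from the plan, which named the transcription start. The value of a window was the mean of its fragments weighted by overlap, on chromosome arms 2L, 2R, 3L, 3R, 4 and X, which held 373710 fragments. Of 29862 windows, 284 without reads and 1 with under 50% of its length covered were left out, which left 29577 windows of 17483 genes.

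Groups, comparisons, the rule for named genes, the gene lists and the alternatives were chosen before the data were examined, except where an addition is named. Window values were fitted with limma 3.58.1 in R 4.3.3 as a group means model with trend and robust empirical Bayes, and p-values were adjusted by Benjamini-Hochberg over all windows. The 17 fusion libraries of the 8 groups with at least 2 files shared 1 fit with 9 residual degrees of freedom. The 6 Dam-alone libraries shared another with 3, on log2 of RPM plus a pseudocount of 0.175. A window was called bound at an adjusted p under 0.05 against 0 and a group mean of at least 1, and called changed at an adjusted p under 0.05 and an absolute difference of at least 0.5. Groups with 1 library were given no test. Named windows were the 10 largest rises and the 10 largest falls past the threshold in which every library of a group lay on the same side of every library of the other, with starts within 2000 bp taken as 1 locus. For bound windows the 10 highest group means were eligible, and for single libraries the 5 largest differences each way. Members of the fixed lists could be named whether or not they passed.

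The 19 gene lists covered tRNA genes, 5S rRNA genes, other Pol III genes (U6, U6atac, 7SL, RNase P and RNase MRP RNA), Pol II snRNA genes, snoRNA genes, cytosolic ribosomal protein genes, sex determination, dosage compensation, neuronal, glial, neuroblast, muscle, haemocyte and fat body, axon guidance, temporal and mushroom body neuron, immediate early and Arc, pre-mRNA splicing factor, Pol III machinery and translation factor genes. For sex determination 15 of 16 symbols matched the annotation, for splicing factors 27 of 29 and for Pol III machinery 15 of 22. Lists were tested with limma's camera at a preset correlation of 0.01, after members were thinned to starts at least 1000 bp apart, with adjustment over 190 tests for the comparisons and 152 for the bound windows. With an estimated correlation the lowest adjusted p was 0.944 among the comparisons and 0.832 among the bound windows, so every list call printed here holds only at the preset correlation.

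Sites were called per library with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A site was a run of consecutive fragments over the library's 95th percentile whose length had a false discovery rate under 0.01 against 20 shuffles. Sites of a group were those of replicate 1 that overlapped a site of replicate 2 by at least 50% of the shorter. Chance overlap between sites was taken from 100 random placements, or 20 for sites of single libraries. Random shares near gene ends and tRNA genes came from a single placement. A further set, called in both the female and the male Sxl library, was used to compare groups because neither library entered the fit. Intervals on shares of sites are exact Clopper-Pearson at 95% and cover counting error only. Figures were drawn with matplotlib 3.10.9 and tables were read in R with version 1.17.8 of data.table.

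The pipeline was tested on simulated data. With 100 windows changed by 1 log2 unit, limma recovered 45% in the comparison of Sxl in Polr3E RNAi with Sxl and 37% in that of the N-terminal truncation with Sxl. At 2 log2 units it recovered 87% and 76%. False calls made up 5.04% and 8.87% of calls. For Dam alone in Polr3E RNAi it recovered 0% at 1 log2 unit and 2% at 2 log2 units. The site caller recovered 98.2% of planted runs of 6 fragments raised by 4 SD, with 0.41% of called sites false. The simulated noise was independent between fragments, and the shuffles also break up any likeness of neighbours. The false share among sites of these data was therefore not measured.

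The alternatives were quantile normalization of all fragments, windows of 1000 bp to either side, windows touched by at least 4 fragments, a fit of the compared groups alone, each replicate left out in turn, a replicate block, a pseudocount at the median window value, a filter that removed the lowest 25% of windows, sites over the 99th percentile, an overlap of 1 bp, and sites of the female library alone. Sites of single libraries, a crossed pairing of the Dam-alone libraries and a replicate block over all fusion libraries were added after seeing the data. The block rests on the data, since no label says what a number marks and the title of the second Sxl library has none, so file order was used for it. Deviations of replicates with the same number correlated at 0.11 to 0.80 over every pair of fusion groups with 2 libraries, Sxl included. Those of Sxl in Polr3E RNAi correlated at -0.45 to -0.08 with the others, so its libraries were given no block. Comparisons of different fusions with Sxl share the same Sxl libraries, so their overlap with each other is not reported.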

Results

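Binding of the RNA-binding protein Sxl (Sex-lethal) and of Polr3E, a subunit of RNA polymerase III, to DNA was profiled by DamID in larval neurons. The Sxl groups were Sxl (2 libraries), Sxl in female and in male neurons (1 library each), N-terminal and C-terminal truncations of Sxl (2 libraries each), Sxl_RNA (2 files with equal values, used as 1 library) and Sxl_GS (1 library). Sxl was also profiled in Polr3E RNAi (3 libraries). Polr3E, Tra, U1 and x16 had 2 libraries each and U2af50 had 1. Dam alone was profiled without RNAi, in Polr3E RNAi and in Polr3A RNAi, with 2 libraries each. Values of fusion libraries are log2 ratios of fusion over Dam alone in 1000 bp windows at gene ends, on BDGP6 coordinates, given as mean ± SD. Differences are given with the standard error of the limma fit. Ratio and RPM files give no read counts, and the read depth of those libraries is not given. Across the 29577 windows, the pair of Sxl libraries correlated at r = 0.88 and the pair of Polr3E libraries at r = 0.74. Windows are not independent replicates. Other pairs were at 0.93 (N-terminal truncation), 0.89 (C-terminal truncation), 0.73 (x16), 0.64 (U1) and 0.44 (Tra). Some fusions with the same library number correlated above their own pairs. For numbers 1 and 2, the truncations had 0.98 and 0.97 with each other, and U1 and x16 had 0.75 and 0.92. Polr3E and Sxl had 0.39 and 0.72, by file order.

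Where Sxl was found on DNA was the first question. The highest Sxl signals lay at CG5402 on 3R (27502023 to 27503023), at 7.85 ± 0.95 (SD, n = 2; adjusted p = 2.4e-06), and at CG15404 on 2L (3173738 to 3174738), at 7.61 ± 0.16 (adjusted p = 6e-08). Both are uncharacterised protein-coding genes. CG7220 (7.35) and CG12715 (7.34) came next. The salivary glue genes Sgs4 and Sgs8, whose products are made in the larval salivary gland, were also among the 10 highest, at 7.26 ± 0.07 and 7.01 ± 0.12. The PDGF and VEGF receptor gene Pvr had 7.04 ± 0.77 at its high end. The others among the 10 highest were CG43110 (7.21), waw (7.11) and CG17362 (6.98 ± 2.52, the widest spread of these). In limma, 9998 windows of 7967 genes were bound by Sxl, among 17483 genes with a window. Of these 16.4% lay on the X chromosome, which held 15.6% of the windows tested. After quantile normalization 6547 windows were bound.

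Genes of the sex determination and dosage compensation pathways that Sxl controls through RNA were among the bound ones. The high end of Sxl itself had 4.07 ± 1.81, that of tra2 had 4.32 ± 0.09, and tra had 1.62 ± 0.69. At msl-2, whose translation Sxl represses in females, the high end had 3.05 ± 0.03. The helicase gene mle had 3.74 ± 0.56 at its high end and msl-1 had 2.20 ± 0.43 at its low end. Of the sex determination genes 10 of 15 were bound (adjusted p = 0.473 against all windows) and of the dosage compensation genes 6 of 8 (adjusted p = 0.438). As lists, neither stood above the other windows.

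Genes for the translation and RNA-processing machinery stood above other windows in Sxl libraries. Among cytosolic ribosomal protein genes 82 of 92 were bound, with a median of 2.08 (adjusted p = 6.9e-09 by camera at the preset correlation). Translation factor genes followed with 15 of 18 (adjusted p = 0.000457), among them eIF4A at 4.75 ± 0.88 and eEF1beta at 3.56 ± 0.04. Of snoRNA genes 169 of 274 were bound (adjusted p = 0.000457), of splicing factor genes 22 of 27 (adjusted p = 0.00105) and of tRNA genes 160 of 290, with a median of 1.03 (adjusted p = 0.00536). These counts were the same when adjusted over the list alone. Of these calls none was kept with an estimated correlation (adjusted p = 0.832 with an estimated correlation). The RNase MRP RNA gene had 5.92 ± 0.89 and 7SLRNA:CR32864, a signal recognition particle RNA gene, had 3.05 ± 0.28. Other Pol III genes were bound in 5 of 8 cases (adjusted p = 0.162), Pol III machinery genes in 8 of 15 (adjusted p = 0.229) and Pol II snRNA genes in 8 of 21 (adjusted p = 0.351). Binding at 5S rRNA genes could not be judged, since 60 of 96 genes had a window and most of these windows held almost no signal. Their Dam-alone median was -2.44 without RNAi, and in Polr3A RNAi it was -2.52, the value of a window without signal. Of these 60, limma called 0 (adjusted p = 0.0659), where 18541 of all windows differed from 0 at an unadjusted p under 0.05.

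Cell-type genes did not stand above other windows as lists. Neuronal genes were bound in 9 of 29 cases (adjusted p = 0.932), with elav at 3.88 ± 0.40 at its high end and Syx1A, a synaptic syntaxin gene, at 2.66 ± 0.51. Glial genes were bound in 4 of 14 cases (adjusted p = 0.412), neuroblast genes in 3 of 15 (adjusted p = 0.0531, on the low side), muscle genes in 8 of 14 (adjusted p = 0.555) and haemocyte and fat body genes in 5 of 12 (adjusted p = 0.229). Axon guidance genes were bound in 13 of 25 cases (adjusted p = 0.832), with Ptp10D at 5.50 ± 0.64. Temporal and mushroom body neuron genes were bound in 10 of 18 cases (adjusted p = 0.237), with mamo at 5.59 ± 0.69. Immediate early and Arc genes were bound in 5 of 7 cases (adjusted p = 0.195), with kay, the Fos gene, at 4.12 ± 0.44, Arc2 at 4.12 ± 0.11 and Arc1 at 3.78 ± 0.41.

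Polr3E was profiled to find where RNA polymerase III sits in the same neurons. The highest Polr3E signal lay at CG15404 (4.62 ± 0.39), and the other 9 of the 10 highest were a mixture of tRNA genes, which RNA polymerase III transcribes, and protein-coding genes. On X, tRNA:Arg-TCG-3-1 (14015739 to 14016739) had 3.74 ± 0.57 (SD, n = 2; adjusted p = 5.4e-07), and tRNA:Ser-GCT-2-5 on 3R had 3.63 ± 0.14 (adjusted p = 0.000243). tRNA:Arg-ACG-1-2 had 3.48 ± 0.02. The protein-coding genes were Ntan1 (3.61), shu (3.58), Spag1 (3.57), lama (3.53), Eig71Ee (3.49) and CG4239 (3.47). Below these, the U6 genes snRNA:U6:96Aa, snRNA:U6:96Ab and snRNA:U6:96Ac had 2.98, 3.08 and 2.99, and snRNA:U6atac had 1.63. In limma, 4762 windows of 4185 genes were bound, and 18.4% of these lay on X. The tRNA genes stood above all windows, with 212 of 290 bound and a median of 1.51 (adjusted p = 4.3e-16, and adjusted p = 0.832 with an estimated correlation). Of these, 212 also passed when adjusted over the list alone. Other Pol III genes were bound in 6 of 8 cases. Most 5S rRNA windows held almost no signal, so binding there was not judged. The highest Polr3E values there were 0.96 at 5SrRNA:CR33417, 0.75 at 5SrRNA:CR33451, 0.61 at 5SrRNA:CR33450 and 0.56 at 5SrRNA:CR33452, under the mean of 1 asked of a bound window. Sxl had -0.08 at 5SrRNA:CR33417, 0.48 at 5SrRNA:CR33451, 0.46 at 5SrRNA:CR33450 and 0.40 at 5SrRNA:CR33452, and these genes were chosen after their values were seen. Neuroblast genes lay below other windows (adjusted p = 0.00116, and adjusted p = 0.832 with an estimated correlation), with 1 of 15 bound (1 adjusted over the list alone).

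The signal at tRNA genes was compared over all fusion groups. Its mean over libraries was 1.48 ± 0.23 for Polr3E, 1.01 ± 0.05 for Sxl, 0.57 ± 0.23 for the N-terminal truncation and 0.59 ± 0.02 for the C-terminal truncation. Single libraries had 1.33 for Sxl in female neurons, 1.29 for Sxl in male neurons, 0.96 for Sxl_RNA and 0.49 for Sxl_GS, and the Polr3E libraries had 1.32 and 1.64, so the ranges of Polr3E and female Sxl met. In Polr3E RNAi the Sxl signal at tRNA genes was 0.34 ± 0.11 (n = 3). The other fusions were lower, at 0.24 for x16, 0.17 for U1, 0.06 for U2af50 and -0.13 for Tra.

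**Figure D1:**
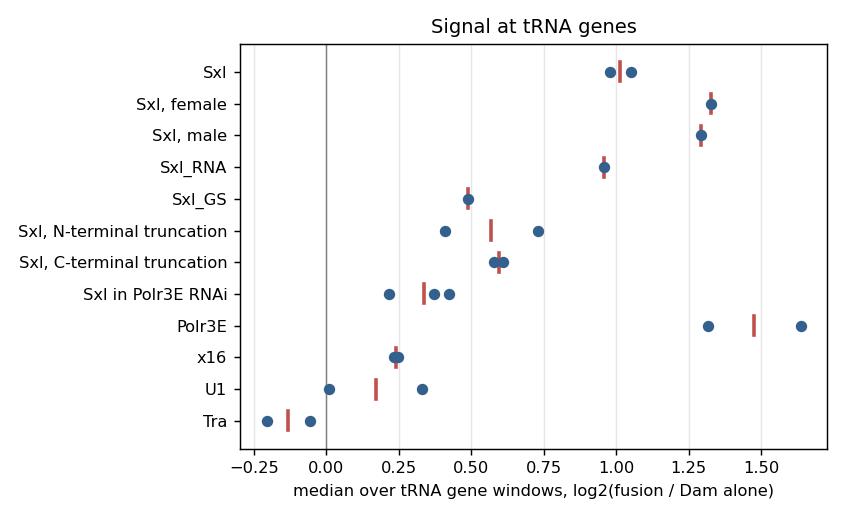
Median log2 ratio of fusion over Dam alone at tRNA gene windows (x axis) for each group of fusion libraries (y axis), with a point per library and a bar at the group mean. Polr3E has the highest group mean at 1.48, Sxl has 1.01 and Sxl in Polr3E RNAi has 0.34.

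The other fusions were read in the same way. The N-terminal truncation of Sxl bound 7464 windows and the C-terminal truncation 6083, with CG17362 highest in both (8.41 ± 0.60 and 6.90 ± 0.72), and the glial receptor gene moody at 7.21 ± 0.02 and 5.98 ± 0.70. Of their bound windows, 7012 and 5927 were also bound by Sxl, where chance would give 2523 and 2056. The SR protein x16 bound 2120 windows, among them Thor, the 4E-BP gene, at 2.61 ± 0.56, Pig1 at 2.62 ± 0.75 and CG13949 at 2.86 ± 0.69. Its lists above other windows were cytosolic ribosomal protein genes (42 of 92, 46 adjusted over the list alone; adjusted p = 1.1e-11), snoRNA genes (92 of 274, 113 adjusted over the list alone; adjusted p = 1.2e-09) and splicing factor genes (6 of 27, 7 adjusted over the list alone; adjusted p = 0.00144), each with an adjusted p = 0.832 with an estimated correlation. Without x16 replicate 1, limma called 0 windows, with 1813 at an unadjusted p under 0.05. Sxl in Polr3E RNAi bound 3967 windows, with the Wnt effector gene pan at 3.78 ± 0.38 (n = 3), tx at 3.71 ± 0.28 and Cad99C at 3.50 ± 0.29. Polr3E and Sxl shared 3850 bound windows, where chance would give 1610. The Dam-alone denominator of each ratio is not given in the sources used here, so part of each excess may come from shared controls. For Tra limma called 0 bound windows (3919 at an unadjusted p under 0.05) and for U1 also 0 (6020). After quantile normalization these counts were 2350 for Tra, 3987 for U1 and 4347 for x16. That step gives every library the same distribution and stretches narrow ones, so these rises do not by themselves show binding. Nor do the counts of 0 show that Tra and U1 did not bind. Window values had an SD of 0.30 and 0.36 in Tra, 0.29 and 0.50 in U1, and 1.37 and 1.53 in Sxl libraries. All of them shared 1 fit, and a mean of at least 1 is harder to reach in narrow libraries.

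Runs of fragments with a high signal gave sites. There were 1335 Sxl sites and 611 Polr3E sites in both libraries of the group. Of the Sxl sites 65.0% lay within 500 bp of a gene end (40.7% in a single random placement). A share of 15.3% overlapped a Polr3E site (exact Clopper-Pearson interval 13.4% to 17.3%), against 1.27% at random. Sites of x16 overlapped 38.9% of the Sxl sites (2.17% at random), sites of U1 20.1% (1.50%) and sites of Tra 2.10% (0.67%). Random runs were placed without regard to gene ends, and an excess over them was not particular to Polr3E. With sites of single libraries these were 48.5% and 57.2% for x16, 24.3% and 51.5% for U1, and 4.19% and 15.7% for Tra, a reading chosen after the data were seen. The truncations overlapped 73.7% (N-terminal) and 71.5% (C-terminal). Single libraries of Sxl in Polr3E RNAi overlapped 32.1%, 29.1% and 30.6% (3.07%, 2.73% and 3.18% at random). The overlap with Polr3E fell to 11.5% without Sxl replicate 2 and was 21.8% and 37.8% with the sites of the first or second Polr3E library alone. At the 99th percentile it was 4.60%. Sites within 1 kb of a tRNA gene made up 11.1% of Polr3E sites (68 of 611, 0.49% at random) and 1.50% of Sxl sites (20 of 1335, 1.05% at random). These random shares came from a single placement, so they have no spread to set the Sxl share against. Of 290 tRNA genes, 126 had a Polr3E site within 1 kb and 39 had a Sxl site. On X lay 32.4% of Polr3E sites and 19.9% of Sxl sites, where 18.0% of fragments lie.

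A set of 1422 sites, called in both the female and the male Sxl library, was used to compare groups. The median signal at these sites was 4.37 ± 0.27 for Sxl, 3.46 ± 0.31 for the N-terminal truncation, 2.76 ± 0.49 for the C-terminal truncation and 1.39 ± 0.20 (n = 3) for Sxl in Polr3E RNAi. Polr3E had 1.25 ± 0.46, x16 1.15 ± 0.24, U1 0.80 ± 0.64 and Tra -0.17 ± 0.27. Relative to Sxl, the median difference was -2.96 for Sxl in Polr3E RNAi, where 1331 sites were lower and 18 higher in limma, and -1.10 after quantile normalization, where 727 were lower and 65 higher. For the truncations it was -0.95 (N-terminal, 385 lower and 9 higher) and -1.61 (C-terminal, 1137 lower and 2 higher). These calls depended on single libraries, with 5 lower and 0 higher left (291 at an unadjusted p under 0.05) without N-terminal truncation replicate 1, and 518 lower without C-terminal truncation replicate 1. With a replicate block the N-terminal counts were 806 and 29. After quantile normalization the medians were -0.38 and -0.33 with 0 sites called in limma (76 and 72 at an unadjusted p under 0.05). Tra differed by -4.57, U1 by -3.58, x16 by -3.19 and Polr3E by -3.13.

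**Figure D2:**
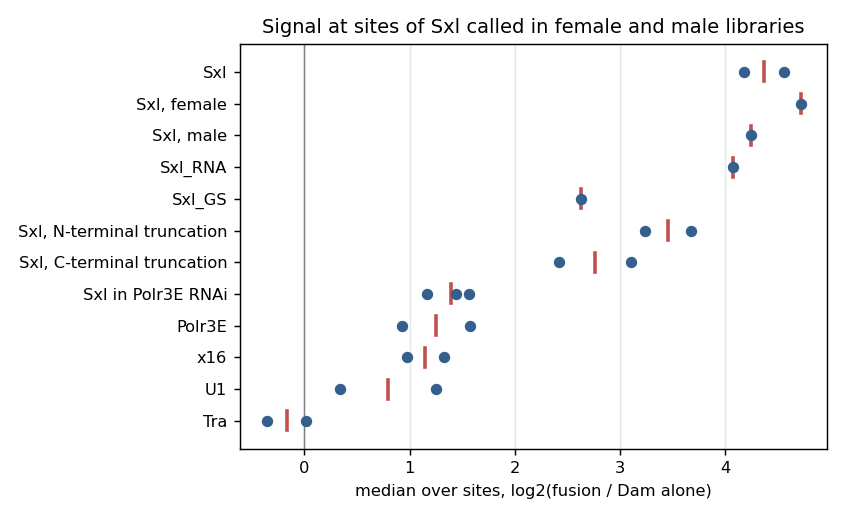
Median log2 ratio of fusion over Dam alone at the 1422 sites called in both the female and the male Sxl library (x axis) for each group (y axis), with a point per library and a bar at the group mean. The 3 libraries of Sxl in Polr3E RNAi lie between 1.17 and 1.56, below every library of Sxl and of its truncations.

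Polr3E and Sxl were compared to tell which genes carry more of either. At tRNA:Arg-ACG-1-10 on 3R (8140506 to 8141506) Polr3E was higher by 3.18 (SE 0.34, adjusted p = 5.7e-05), with 2.88 ± 0.13 against -0.31 ± 0.38. tRNA:Arg-ACG-1-2 was higher by 3.16 (SE 0.29, adjusted p = 2.7e-05) and tRNA:Arg-TCG-3-1 by 2.87 (SE 0.27, adjusted p = 3.0e-05). Among protein-coding genes, Polr3E was higher at shu, a gene of the piRNA pathway, by 3.10 (SE 0.42) and at CG13857 (3.09), Ptr (3.05), CG10725 (2.99), the serine protease gene Ser8 (2.80), CG42590 (2.78) and CG13727 (2.57). Other Pol III genes went both ways, with 3 of 8 higher and 3 lower (4 and 4 adjusted over the list alone; median -0.78, adjusted p = 0.706). Of these, snRNA:U6:96Aa was higher by 2.81 (SE 0.24), snRNA:U6:96Ab by 1.78 (SE 0.18) and snRNA:U6:96Ac by 0.90 (SE 0.19), whereas RNaseMRP:RNA was lower by -4.27 (SE 0.45), 7SLRNA:CR32864 by -1.72 (SE 0.47) and 7SLRNA:CR42652 by -0.78 (SE 0.10). Sxl was the higher of the pair at CG31075, by -6.46 (SE 0.54, adjusted p = 2.0e-05) as Polr3E minus Sxl, and at CG3770 (-6.40), lncRNA:CR32218 (-6.16), the ribosome recycling gene pix (-6.09), the transcription factor gene Mondo (-6.02), Cap-H2 of condensin II (-5.97), lncRNA:CR44867 (-5.91), CG3909 (-5.88), the m6A reader gene Ythdf (-5.85) and CG5402 (-5.73).

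Of all windows, 1008 were higher for Polr3E and 7832 higher for Sxl, and after quantile normalization these counts were 875 and 2430. In a fit of both groups alone they were 37 and 1155, and without Sxl replicate 2 they were 1909 and 7270. The median of all windows was -0.21, and -0.04 after quantile normalization. The tRNA list was shifted towards Polr3E (median 0.21, adjusted p = 8.1e-10, and adjusted p = 0.944 with an estimated correlation), with 106 genes higher and 60 lower of 290 (111 and 67 adjusted over the list alone). Of 60 5S rRNA genes 2 were higher (2 adjusted over the list alone; adjusted p = 0.00198, and adjusted p = 0.944 with an estimated correlation), namely 5SrRNA:CR33417 by 1.04 (adjusted p = 0.000419) and 5SrRNA:CR33418 by 0.51 (adjusted p = 0.000281). The median of this list was 0.01, so windows with little signal in either group stood above a median of all windows below 0. Relative to all windows it was 0.22, and 0.04 after quantile normalization. Cytosolic ribosomal protein genes were shifted towards Sxl (median -1.33, adjusted p = 5.8e-07), with 71 lower (74 lower and 1 higher adjusted over the list alone). Translation factor genes were lower in 14 of 18 cases (14 adjusted over the list alone; adjusted p = 0.00865), and both of these lists had an adjusted p = 0.944 with an estimated correlation. Of the Pol III machinery genes 6 were lower, with Polr3F at -4.81 (adjusted p = 1.2e-05), Brf at -3.99 and Maf1 at -3.90, and 1 was higher (6 and 1 adjusted over the list alone; adjusted p = 0.779), and the list changed sides of the median of all windows after quantile normalization. Sex determination genes had 8 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.309), with tra2 at -4.39. Neuronal genes had 9 lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.756), and changed sides of that median as well.

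The truncations were profiled to ask which part of Sxl its binding needs. Against Sxl, the N-terminal truncation was higher at CG15601 on X (15710147 to 15711147) by 3.24 (SE 0.60, adjusted p = 0.0149), at danr, a transcription factor gene of the antenna and eye, by 2.87 (SE 0.39, adjusted p = 0.00467), and at CG42674 (2.77), the homeobox gene H2.0 (2.67), mmy (2.34), lncRNA:CR46035 (2.28), the ankyrin gene Ank2 (2.26), the gap junction gene Inx2 (2.16), spri (2.14) and tRNA:Ser-AGA-2-1 (2.13). It was lower at CG42455 by -4.07 (SE 0.47, adjusted p = 0.00371), at the octopamine receptor gene Octbeta1R by -3.46 (SE 0.32, adjusted p = 0.0015), and at CG12091 (-3.33), CG12316 (-3.23), MFS18 (-3.18), CG7966 (-2.99), the kinase gene Slik (-2.98), the splicing factor gene Prp39 (-2.96), CG9399 (-2.94) and CG30371 (-2.93). In all, 113 windows were higher and 1381 lower. Cytosolic ribosomal protein genes were lower in 23 cases (44 adjusted over the list alone; adjusted p = 2.5e-07), splicing factor genes in 9 (16 adjusted over the list alone; adjusted p = 0.000221), snoRNA genes in 32 (75 adjusted over the list alone; adjusted p = 0.00024), other Pol III genes in 2 (4 adjusted over the list alone; adjusted p = 0.0195) and translation factor genes in 4 (7 adjusted over the list alone; adjusted p = 0.00198). Neuroblast genes were shifted up (2 higher, 5 adjusted over the list alone; adjusted p = 0.00468), with a median of 0.07 that became -0.02 after quantile normalization, where the list still lay above the median of all windows. The tRNA genes had 1 higher and 20 lower (2 and 31 adjusted over the list alone; adjusted p = 0.0795). None of these held with an estimated correlation (adjusted p = 0.944 with an estimated correlation). Without N-terminal truncation replicate 1 only 6 windows passed, and without Sxl replicate 2 there were 3377, of which 1068 were higher. With a replicate block 294 were higher and 3982 lower. After quantile normalization limma called 0 windows (2851 at an unadjusted p under 0.05), and a fit of both groups alone also called 0 (2586).

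The C-terminal truncation was higher than Sxl at danr by 1.64 (SE 0.39, adjusted p = 0.0182), at the carbonic anhydrase gene CAH5 by 1.50 (SE 0.13, adjusted p = 0.000676), at nej, the CBP gene, by 1.41 (SE 0.29), at shd by 1.27 and at the Cdc25 gene stg by 1.22. Smaller rises lay at Pex7 (1.08), mre11 (1.06), CG32182 (1.01), CR43281 (0.99) and lncRNA:CR42755 (0.97). It was lower at CG12316 by -3.90 (SE 0.83, adjusted p = 0.0119), at CG12091 by -3.83 (SE 0.38, adjusted p = 0.000897), and at asRNA:CR46194 (-3.72), the hnRNP gene sqd (-3.61), the ribosomal protein gene RpS3 (-3.57), rdx (-3.57), the nuclear envelope gene koi (-3.53), CG4239 (-3.50), ATPCL (-3.45) and the RNA export gene Nxf3 (-3.42). In all, 56 windows were higher and 3736 lower. The count of higher windows was 480 without Sxl replicate 2 and 27 without C-terminal truncation replicate 1, and with a replicate block 130 were higher and 6254 lower. Lower lists were cytosolic ribosomal protein genes (51 lower, 62 adjusted over the list alone; median -0.99, adjusted p = 8.1e-10), translation factor genes (10 lower, 11 adjusted over the list alone; adjusted p = 7.5e-05), snoRNA genes (78 lower, 112 adjusted over the list alone; adjusted p = 0.000215) and splicing factor genes (16 lower, 17 adjusted over the list alone; adjusted p = 0.000221), each with an adjusted p = 0.944 with an estimated correlation. Neuroblast genes were shifted up here too (adjusted p = 0.0388 by camera at the preset correlation). Their median relative to all windows was 0.13, and 0.06 after quantile normalization, and the call was not kept with an estimated correlation. The tRNA genes had 55 lower (66 lower and 2 higher adjusted over the list alone, and adjusted p = 0.125). Without C-terminal truncation replicate 1 the count of changed windows was 766. After quantile normalization limma called 0 windows (2697 at an unadjusted p under 0.05), and a fit of both groups alone called 0 (3585).

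Between the truncations, 1 window passed. lncRNA:CR42657 on X (9687689 to 9688689) was lower in the N-terminal truncation by -1.88 (SE 0.21, adjusted p = 0.0453), with 0.55 ± 0.00 against 2.44 ± 0.59. It passed neither after quantile normalization (0 windows in limma, 253 at an unadjusted p under 0.05) nor without N-terminal truncation replicate 1 (0, with 1578) or replicate 2 (0, with 1105), and 5 windows passed without C-terminal truncation replicate 1. At an unadjusted p under 0.05 there were 1536 windows. Cytosolic ribosomal protein genes were higher in the N-terminal truncation (median 0.24, adjusted p = 0.00694), and translation factor genes too (adjusted p = 0.0195), with 0 genes of either list called by limma (0 adjusted over the list alone), and both had an adjusted p = 0.944 with an estimated correlation. The ribosomal protein median relative to all windows was 0.21, and 0.01 after quantile normalization. Adjusted over the list alone, 2 muscle genes and 1 Pol III machinery gene were higher. At windows bound by Sxl, the median of N-terminal minus C-terminal truncation was 0.38 between libraries numbered 1 and 0.32 between those numbered 2, so a small count of called windows does not show that the truncations bound alike. After quantile normalization the medians against Sxl at the 1422 sites were -0.38 (N-terminal) and -0.33 (C-terminal), so the difference did not outlast it there.

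Sxl in Polr3E RNAi was compared with Sxl to ask whether Sxl binding depends on Polr3E. Sxl signal was lower in Polr3E RNAi at CG15404 by -7.92 (SE 0.45, adjusted p = 2.2e-06), with -0.30 ± 0.20 (n = 3) against 7.61 ± 0.16 (n = 2). It was lower at the salivary glue genes Sgs4 by -6.84 (SE 0.37, adjusted p = 1.9e-06) and Sgs8 by -6.61 (SE 0.39), at the ecdysone-induced gene Eig71Ee by -6.61 (SE 0.44), at CG5402 by -6.74 (SE 0.92), at CG7220 (-6.62), CG12715 (-6.51), the Hippo pathway gene sav (-6.45), the phosphate transporter gene Picot (-6.44) and CG45116 (-6.24). It was higher at lncRNA:CR42755 by 3.73 (SE 0.25, adjusted p = 4.5e-06), at the cuticle genes Lcp65Af by 3.54 (SE 0.24), TwdlF by 2.94 (SE 0.20) and Gasp by 3.10 (SE 0.31), at jigr1 by 3.51 (SE 0.38) and at the RNA-binding protein gene lin-28 by 3.07 (SE 0.23). Further rises lay at CG30427 (3.12), wwk (2.93), CG13579 (2.91) and CG14439 (2.91).

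Sex determination genes had 10 of 15 lower and 0 higher (10 adjusted over the list alone; adjusted p = 0.672). The high end of msl-2 was lower by -2.69 (SE 0.31, adjusted p = 6.4e-05), that of Sxl by -2.47 (SE 0.60, adjusted p = 0.00564), that of tra2 by -1.92 (SE 0.41, adjusted p = 0.00271), and ix by -3.22 (SE 0.39). In dosage compensation, mle was lower at its high end by -3.16 (SE 0.44) and higher at its low end by 1.00 (SE 0.32, adjusted p = 0.0225), with 3 genes lower, 1 higher and 1 with both (3 and 1 adjusted over the list alone; adjusted p = 0.666). Among neuronal genes 5 were lower, 2 higher and 2 had both (5 and 2 adjusted over the list alone; adjusted p = 0.0636). The adenylyl cyclase gene rut was lower by -5.16 (SE 0.35, adjusted p = 4.7e-06) and elav by -1.64 (SE 0.30, adjusted p = 0.000939), while Syn, the synapsin gene, was higher at its low end by 1.34 (SE 0.47, adjusted p = 0.033). Neuroblast genes were shifted up (median 0.32, adjusted p = 0.000221, and adjusted p = 0.944 with an estimated correlation), with 8 of 15 higher and 3 lower (8 and 3 adjusted over the list alone). Of these, stg was higher by 1.95 (SE 0.21), grh by 1.55 (SE 0.40), l(1)sc by 1.38 (SE 0.16), mira by 1.05 (SE 0.27) and wor by 1.01 (SE 0.13), whereas pnt was lower by -2.30 (SE 0.27). After quantile normalization the neuroblast median was 0.35. Dam-alone signal at the same list was lower in Polr3E RNAi, by -0.76 relative to all windows (adjusted p = 3.2e-06, and adjusted p = 0.944 with an estimated correlation), and a lower control would raise the ratio by itself.

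Cytosolic ribosomal protein genes were lower in 80 of 92 cases and higher in 2 (82 and 2 adjusted over the list alone; median -1.51, adjusted p = 4.4e-07), snoRNA genes in 196 of 274 (210 adjusted over the list alone; adjusted p = 0.000234), translation factor genes in 15 of 18 (14 adjusted over the list alone; adjusted p = 0.00166) and splicing factor genes in 21 of 27 (22 adjusted over the list alone; adjusted p = 0.00468), each with an adjusted p = 0.944 with an estimated correlation. Each of these lists stood above other windows in Sxl libraries. Relative to all windows, the ribosomal protein median was -1.24, and -0.51 after quantile normalization. These values were -1.59 and -0.47 for Tra against Sxl, -1.13 and -0.40 for Polr3E, -1.12 and 0.03 for U1, and -1.13 and -0.03 for x16. A fall of this list against Sxl is therefore not particular to the knockdown. The tRNA genes had 139 lower and 7 higher (140 and 7 adjusted over the list alone). Their median of -0.51 was not below that of all windows by camera (adjusted p = 0.317). RNaseMRP:RNA was lower by -4.46 (SE 0.41, adjusted p = 1.7e-05). Pol III machinery genes had 9 lower (9 adjusted over the list alone; adjusted p = 0.334), with Brf at -4.53 (SE 0.30), Maf1 at -3.54 (SE 0.40) and Polr3E itself at -0.68 (SE 0.23, adjusted p = 0.0321). Immediate early and Arc genes had 4 lower (adjusted p = 0.522), with kay at -3.88 (SE 0.30) and Arc2 at -3.19 (SE 0.26). In axon guidance 10 were lower and 5 higher (adjusted p = 0.447), in the temporal and mushroom body list 9 and 1 (adjusted p = 0.677), and among glial genes 7 and 2 (adjusted p = 0.576), and all of these counts were the same adjusted over the list alone. Glial, temporal and mushroom body, and immediate early lists changed sides of the median of all windows after quantile normalization. In all, 1901 windows were higher and 10100 lower. After quantile normalization these were 1843 and 4832, and the median of all windows was -0.19, against -0.27 before.

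**Figure D3:**
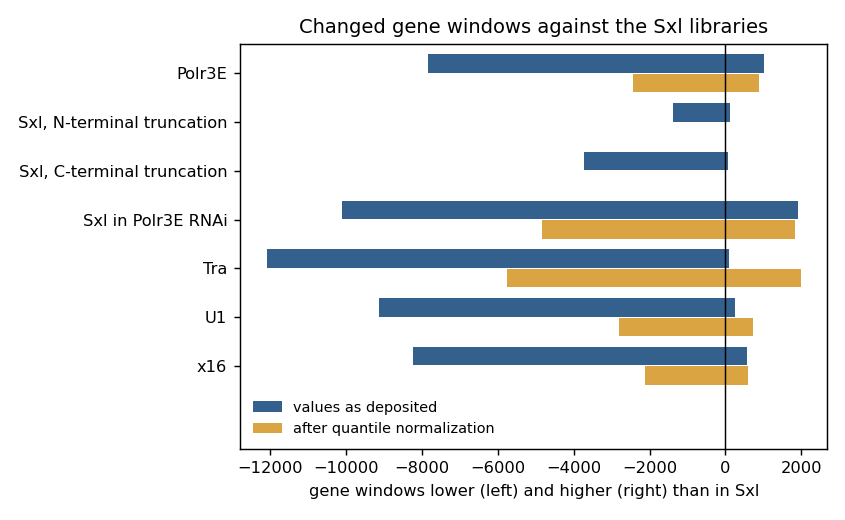
Number of gene windows lower (left of 0) and higher (right of 0) than in Sxl for each compared group (y axis), with values as deposited and after quantile normalization. Sxl in Polr3E RNAi has 10100 lower windows as deposited and 4832 after quantile normalization, and the truncations have 0 after it.

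Tra, U1 and x16 were compared with Sxl to tell how far the pattern belongs to Sxl. Tra was lower than Sxl at Pdi, the protein disulphide isomerase gene, by -7.92 (SE 0.45, adjusted p = 1.1e-06), at lncRNA:CR32218 by -7.91, Vps13 by -7.60, CG5402 by -7.47, Mst85C by -7.44, CG43110 by -7.44, waw by -7.42, Cap-H2 by -7.31, Pvr by -7.27 and Dd by -7.26. It was higher at beta-Man by 1.36 (SE 0.29, adjusted p = 0.00228), CG6962 (0.99), mir-9c (0.90), Culd (0.86), CG12920 (0.85), natalisin (0.85), CG15824 (0.81), CG15005 (0.80) and Nepl10 (0.78). CG15014 was higher by 0.81, and lower by -0.0248 in windows of 1000 bp to either side. In all, 95 windows were higher (249 without Sxl replicate 1, 25 without Tra replicate 1 and 158 with a replicate block) and 12097 lower, and after quantile normalization, which moved the median of all windows from -0.44 to -0.09, 1985 were higher and 5755 lower. The tRNA genes had 195 lower (200 adjusted over the list alone; adjusted p = 0.00035) and cytosolic ribosomal protein genes 83 (85 adjusted over the list alone; adjusted p = 2.5e-07), each with an adjusted p = 0.944 with an estimated correlation.

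U1 was lower than Sxl at CG15404 by -7.68 (SE 0.50, adjusted p = 5.2e-06), at the NF-kappaB gene Rel by -6.93 (SE 0.56), at CG12715 (-6.72), CG5402 (-6.70), Sgs4 (-6.60), Pvr (-6.58), Pdi (-6.41), CG17362 (-6.29), waw (-6.27) and the actin gene Act5C (-6.22). It was higher at CG12496 by 2.25 (SE 0.50, adjusted p = 0.00429), jigr1 (1.76), CG32071 (1.65), the Notch target genes E(spl)m7-HLH (1.44) and E(spl)m8-HLH (1.32), blw (1.43), CG14212 (1.42), ftz (1.31), scu (1.30) and mir-9c (1.29). In all, 258 windows were higher and 9135 lower, with 737 and 2814 after quantile normalization, and 6079 passed without U1 replicate 1. The count of higher windows was 584 without Sxl replicate 1, 121 without U1 replicate 2 and 449 with a replicate block. The lists of tRNA genes (152 lower and 1 higher, 161 and 1 adjusted over the list alone; adjusted p = 0.00781) and cytosolic ribosomal protein genes (68 lower and 1 with both, 71 lower adjusted over the list alone; adjusted p = 0.000151) were lower, though after quantile normalization the ribosomal protein list lay above the median of all windows by 0.03. The neuroblast genes stood above the other windows (2 higher and 3 lower, the same adjusted over the list alone; adjusted p = 0.00737). Each had an adjusted p = 0.944 with an estimated correlation.

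For x16 the rises were at beta-Man by 1.66 (SE 0.29, adjusted p = 0.00108), mir-33 (1.56), CG6763 (1.50), mir-9c (1.50), CG32071 (1.47), the snoRNP gene nop5 (1.45), CG12496 (1.44), Nap1 (1.44), asRNA:CR44049 (1.41) and CG14212 (1.38). The falls were at CG15404 by -6.78 (SE 0.50, adjusted p = 1.1e-05), Rel (-6.69), CG12715 (-6.36), nsl1 (-6.12), rdx (-6.10), Sgs4 (-6.05), Pdi (-6.03), Pvr (-5.98), waw (-5.91) and Hel89B (-5.88). In all, 569 windows were higher and 8242 lower, with 597 and 2132 after quantile normalization. The count of higher windows was 109 without x16 replicate 1, 1047 without x16 replicate 2 and 881 with a replicate block. The tRNA genes had 122 lower (132 adjusted over the list alone; adjusted p = 0.00647) and cytosolic ribosomal protein genes 69 (70 adjusted over the list alone; adjusted p = 0.000116), each with an adjusted p = 0.944 with an estimated correlation. After quantile normalization their medians relative to all windows went from -0.47 to -0.08 for tRNA genes and from -1.13 to -0.03 for ribosomal protein genes. Fits of both groups alone called 0 windows in limma for U1 (8928 at an unadjusted p under 0.05) and for x16 (7940).

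Dam alone in Polr3E RNAi and in Polr3A RNAi, which targets the largest subunit of RNA polymerase III, served as a measure of accessible DNA. In Polr3E RNAi Dam-alone signal was lower at CG3397 by -5.41 (SE 0.28, adjusted p = 0.0327), MEP-1 by -5.11 (SE 0.29), CG31819 by -4.19, tRNA:Ala-CGC-1-2 by -3.99 (SE 0.31), mthl8 by -3.87, CG12384 by -3.67, dpy by -3.63, az2 by -3.44, RpS15 by -3.39 and otk by -3.39. It was higher at CG33296 by 3.72 (SE 0.45, adjusted p = 0.0328), CG5122 (3.58), Octbeta1R (3.53), the odorant receptor gene Or42a (3.49), CG5026 (3.48), CG6435 (3.32), CG43788 (3.21), Nckx30C (3.16), lncRNA:CR44055 (3.12) and Zir (3.01). In all, 1388 windows were higher and 771 lower. Of these, 4.11% of the higher and 26.7% of the lower lay on X, which held 15.6% of the windows tested. Signal on Y, outside these windows, averaged 0.069 and 0.073 RPM per fragment in Polr3E RNAi, against 0.017 and 0.019 without RNAi. Whether the libraries differed in their share of male and female animals was not tested, so falls on X may not come from the RNAi. The tRNA genes were shifted down (median -0.34, with 22 lower and 3 higher, 36 and 7 adjusted over the list alone; adjusted p = 7.5e-05), and neuroblast genes too (median -0.64, with 5 lower, 8 adjusted over the list alone; adjusted p = 3.2e-06). Pol II snRNA genes were shifted down (median -0.89, with 3 lower and 1 higher, the same adjusted over the list alone; adjusted p = 0.0195). Over pairs of libraries their median relative to all windows lay between -1.25 and -0.66. Cytosolic ribosomal protein genes had 8 lower and 3 higher (the same adjusted over the list alone; adjusted p = 0.000234). Each had an adjusted p = 0.944 with an estimated correlation. The median of all windows was 0.12, and 0.00 after quantile normalization, where 695 windows were higher and 784 lower. Without either Polr3E RNAi replicate limma called 0 windows (5190 and 5380 at an unadjusted p under 0.05). Without Dam-alone replicate 1 it called 12516, and without replicate 2 it called 13207.

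In Polr3A RNAi the same genes CG3397 (-5.65, SE 0.28, adjusted p = 0.00746), MEP-1 (-5.44), tRNA:Ala-CGC-1-2 (-4.43), az2 (-4.69) and dpy (-4.39) were among the largest falls, and Or42a (4.44, SE 0.26, adjusted p = 0.00746), Zir (4.38) and CG33296 (4.34) among the largest rises, where the Dam-alone control is shared by both comparisons. Further falls were CG31075 (-5.63), Ugt50B3 (-4.98), Hasp (-4.53), the kinase gene Btk (-4.44) and the histone gene His1:CG33804 (-4.44). Further rises were yellow-g2 (4.41), Qtzl (4.15), CG15712 (3.96), CG15537 (3.92), the ion channel gene ppk21 (3.88), CG17239 (3.88) and CG13117 (3.69). In all, 3525 windows were higher and 5175 lower, against 4675 and 4364 after quantile normalization. That step moved the median of all windows from -0.25 to 0.00. Of the changed windows, 9.30% of the higher and 17.9% of the lower lay on X. Signal on Y averaged 0.050 and 0.046 RPM per fragment, so the limit on falls on X holds here too. The tRNA genes were shifted down (median -0.84, with 94 lower and 10 higher, 100 and 11 adjusted over the list alone; adjusted p = 0.00225, and adjusted p = 0.944 with an estimated correlation). Neuroblast genes had 8 lower and 1 higher (the same adjusted over the list alone; adjusted p = 0.00865), and temporal and mushroom body neuron genes 11 and 1 (13 and 1 adjusted over the list alone; adjusted p = 0.0195), each with an adjusted p = 0.944 with an estimated correlation. The Pol II snRNA genes had 6 lower and 1 higher (the same adjusted over the list alone; adjusted p = 0.246), with a median of -0.86 relative to all windows that lay between -1.35 and -0.30 over pairs of libraries. Without either Polr3A RNAi replicate limma called 0 windows (7534 and 7419 at an unadjusted p under 0.05), without Dam-alone replicate 1 it called 13204 and without replicate 2 it called 19030.

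Groups of 1 library have no test. Between Sxl in female and in male neurons, differences had an SD of 0.58 over windows, against 0.74 between the pair of Sxl libraries, and 2556 windows differed by over 1, against 4690. The largest in the female library were Stt3A (5.24 against 2.27), CG17486 (8.67 against 5.83), Sec61gamma (2.86 against 0.28), SelG (2.53 against 0.19) and the ribosomal protein gene RpL5 (7.63 against 5.31). The largest in the male library were RpLP2 (3.91 against -0.62), CG14561 (1.60 against -2.84), CG5390 (1.31 against -2.44), yellow-d2 (2.47 against -1.12) and 7B2 (1.88 against -1.66). The median difference was 0.00 on X and 0.03 on autosomes. Of the 1335 Sxl sites, 82.0% overlapped a site of the female library and 80.1% one of the male library.

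The Sxl_RNA library differed from the mean of Sxl with an SD of 0.56. It was higher at Kah (3.59 against 0.77), CG6813 (4.05 against 1.37), CG9986 (4.76 against 2.12), the ecdysone-induced gene Eip74EF (3.49 against 0.89) and the kinesin gene Khc (3.78 against 1.24), and lower at CG31075 (1.98 against 5.68), CG34278 (0.98 against 4.66), CG12316 (2.10 against 5.67), CNPYb (1.76 against 4.94) and Octbeta1R (0.89 against 3.95). Sxl_GS differed more, with an SD of 0.89. It was higher at RpL22 (4.90 against 1.21), jigr1 (2.23 against -0.99), CG32071 (2.63 against -0.51), E(spl)m8-HLH (2.32 against -0.74) and CG12496 (1.20 against -1.57), and lower at Gprk2 (-1.65 against 4.23), APC7 (-0.04 against 5.74), Dyrk2 (0.31 against 5.78), CG11999 (0.03 against 5.26) and gw (0.32 against 5.45). At the 1422 sites the medians were 4.08 for Sxl_RNA and 2.63 for Sxl_GS. U2af50 correlated with the Sxl libraries at r = 0.19 and 0.20 across windows. It was higher than Sxl at Pex11ab (1.09 against -0.68), CG2217 (1.18 against -0.57), EDTP (1.16 against -0.37), CG15784 (1.46 against -0.03) and Or43b (1.22 against -0.24), and lower at CG5402 (-0.37 against 7.85), CG12715 (-0.66 against 7.34), CG45092 (-1.02 against 6.73), CG9040 (-1.17 against 6.40) and CG7220 (-0.22 against 7.35).

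Fusions of Polr3E, x16, Tra and Sxl were read at the gene of the fused protein, where sequence of the fusion construct can add to the signal. U1 and U2af50 were not read in this way. The mean over the Polr3E gene was 1.40 ± 0.32 (SD, n = 2) in Polr3E libraries, against 0.33 ± 0.02 in Sxl and 0.76 ± 0.79 in x16 libraries. That over x16 was 0.87 ± 0.40 in x16 libraries, against 0.78 ± 0.11 in Sxl libraries and 1.08 in the male Sxl library. That over tra was -0.08 ± 0.16 in Tra libraries, against 1.44 ± 0.47 in Sxl libraries. At x16 and tra the libraries of that fusion were therefore not the highest. That over Sxl was 1.59 ± 0.31 in Sxl libraries, against 1.12 ± 0.03 in Polr3E libraries. Within Sxl, a stretch of 11 fragments on X (7084458 to 7086180) had a mean of 3.43 ± 0.56 in Sxl libraries, 2.94 ± 0.36 in the N-terminal truncation and 2.30 ± 1.17 in the C-terminal truncation. The female library had 3.08 there, the male library 3.60, Sxl_RNA 3.73 and Sxl_GS 3.92. Signals of the other fusions were low, at 0.07 for Tra, 0.15 for U1, 0.16 for x16 and 0.59 ± 0.19 for Polr3E. Sxl in Polr3E RNAi was low there as well, at 0.67 ± 0.10 (n = 3). The stretch was chosen after its values were seen. It was the run of fragments at 1.5 or more in both Sxl_RNA and Sxl_GS, around their highest fragment in the gene. The values of Sxl_RNA and Sxl_GS there are therefore high by construction. Whether the knockdown lowered Polr3E itself was not analysed here.

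**Figure D4:**
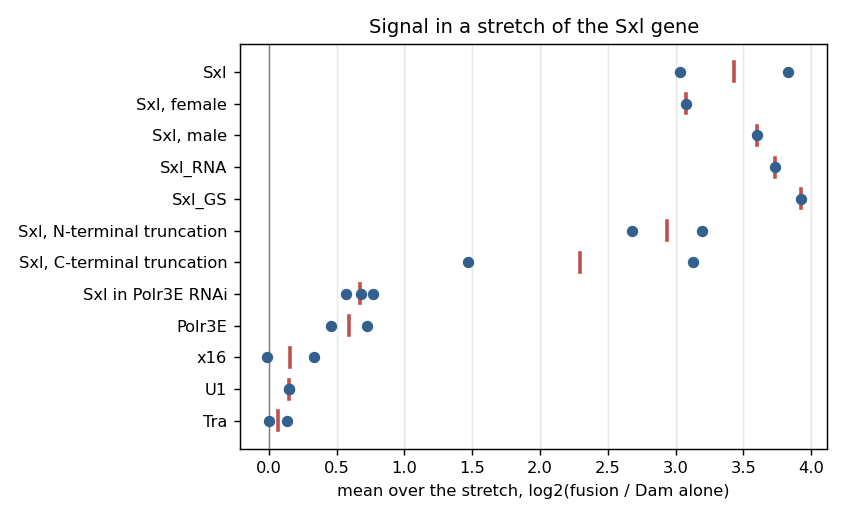
Mean log2 ratio of fusion over Dam alone in the stretch of the Sxl gene (x axis) for each group of fusion libraries (y axis), with a point per library and a bar at the group mean. Sxl has 3.43, while Sxl in Polr3E RNAi has 0.67. Sxl_GS (3.92) and Sxl_RNA (3.73) were used to set the stretch, so they are high by construction.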

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

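The mitochondrial genome was looked at only after its values had been seen, so what follows are values and comparisons, not predictions. It lies outside the gene windows of every comparison above, and it was picked out because Sxl fusion libraries carried a signal there above that of every library of Tra, U1 and x16, used as controls. Over its 28 fragments, the median log2 ratio of fusion over Dam alone was 5.18 ± 0.47 (SD, n = 2) for Sxl, 7.86 for Sxl in female neurons (n = 1), 5.62 for Sxl in male neurons (n = 1), 8.25 ± 0.02 for the N-terminal truncation, 6.28 ± 0.78 for the C-terminal truncation and 2.73 for Sxl_RNA (n = 1). The controls had -0.87 ± 0.13 for Tra, -0.29 ± 0.37 for U1 and -0.25 ± 0.35 for x16. Sxl_GS had 0.32 (n = 1), Polr3E 0.57 ± 0.26 and Sxl in Polr3E RNAi 0.04 ± 0.02 (n = 3). In Dam-alone libraries the mitochondrial genome held 0.0929% and 0.0396% of the signal without RNAi, 0.00864% and 0.00855% in Polr3E RNAi, and 0.00106% and 0.00151% in Polr3A RNAi. No explanation, technical or biological, was tested for this signal.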

How the results depend on the processing

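The crossed pairing of replicates, the replicate block over all fusion libraries and the sites of single libraries alone were chosen after the data were seen and are tests, not predictions. Quantile normalization lowered bound Sxl windows from 9998 to 6547, and raised those of Tra from 0 to 2350, of U1 from 0 to 3987 and of x16 from 2120 to 4347. It lowered changed windows against Sxl to 3305 for Polr3E, 6675 for Sxl in Polr3E RNAi, 7740 for Tra, 3551 for U1 and 2729 for x16. In limma it left 0 for the N-terminal truncation (2851 at an unadjusted p under 0.05), 0 for the C-terminal truncation (2697) and 0 between the truncations (253). Median differences at Sxl sites became -0.38 (N-terminal), -0.33 (C-terminal), -2.19 (Tra), -1.08 (U1), -0.78 (x16), -1.19 (Polr3E) and -1.10 (Sxl in Polr3E RNAi). Quantile normalization gives every fusion library the same distribution of values, so narrow libraries are stretched by construction. Window values had an SD of 0.30 and 0.36 in Tra libraries, against 1.37 and 1.53 in Sxl libraries. The added bound windows of Tra, U1 and x16 therefore do not by themselves show binding. No other cause was tested.

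Windows with at least 4 fragments are fewer by construction. They gave 5685 bound windows for Sxl, 2684 for Polr3E and 180 for U1, and changed windows against Sxl of 5195 for Polr3E, 351 and 1558 for the N-terminal and C-terminal truncations, 6985 for Sxl in Polr3E RNAi, 6896 for Tra, 5147 for U1 and 4832 for x16. Between the truncations limma gave 0 (954 at an unadjusted p under 0.05). Windows of 1000 bp to either side gave 4523 changed windows for Dam alone in Polr3E RNAi, and turned Tra minus Sxl at CG15014 to -0.0248. The cause was not tested.

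Fits of both groups alone have fewer samples to estimate the spread. They gave 1192 changed windows for Polr3E and 7317 for Tra against Sxl, and with limma 0 for the N-terminal truncation (2586 at an unadjusted p under 0.05), 0 for the C-terminal truncation (3585), 0 for U1 (8928), 0 for x16 (7940) and 0 between the truncations (1046). With a block on replicate number in such a fit, limma gave 0 between the truncations (5643), 0 for Dam alone in Polr3E RNAi (2918) and 0 for Dam alone in Polr3A RNAi (10377). The crossed pairing, run for Dam alone in Polr3E RNAi only, also gave 0 (6827). Dam-alone deviations by number correlated at -0.38, -0.09 and 0.26, so pairing there is not established. With a replicate block over all fusion libraries, changed windows against Sxl were 4276 for the N-terminal and 6384 for the C-terminal truncation, and Pol II snRNA genes passed for Tra minus Sxl (adjusted p = 0.046, and adjusted p = 0.927 with an estimated correlation). It changed no other call of a list or named window.

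At the 99th percentile, which keeps fewer and stronger sites, median differences became -6.17 (Tra), -4.94 (U1), -4.38 (x16), -4.49 (Polr3E) and -3.91 (Sxl in Polr3E RNAi), and the overlap of Sxl with Polr3E sites 4.60%. An overlap of 1 bp gave 19.0%, where the looser rule counts more sites by construction.

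Where a replicate was left out, the lone library was taken to vary like those of the other groups. Bound windows ranged over 8670 to 10931 for Sxl, 3281 to 5560 for Polr3E, 0 to 0 for Tra, 0 to 0 for U1 and 0 to 3105 for x16. Changed windows against Sxl ranged over 6277 to 9562 for Polr3E, 6 to 3377 and 766 to 4901 for the N-terminal and C-terminal truncations, 9226 to 13416 for Sxl in Polr3E RNAi, 9966 to 13234 for Tra, 6079 to 11235 for U1 and 7013 to 10639 for x16. They ranged over 0 to 5 between the truncations, 0 to 13207 for Dam alone in Polr3E RNAi and 0 to 19030 in Polr3A RNAi. Median differences at sites ranged over -1.18 to -0.74 (N-terminal), -1.96 to -1.25 (C-terminal), -4.77 to -4.39 (Tra), -4.02 to -3.16 (U1), -3.39 to -3.04 (x16), -3.47 to -2.81 (Polr3E) and -3.13 to -2.82 (Sxl in Polr3E RNAi), and the overlap over 11.5% to 37.8%.

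Named windows were counted once per comparison, so a gene can recur. After quantile normalization 122 kept direction and call and 59 kept the direction alone. In fits of both groups alone these counts were 51 and 90, and in the wider windows 170 and 10 with 1 reversed. Over all tests with a library left out, several per window, they were 574 and 170. Pseudocount, filter on low values and the sites of the female library alone moved 0 of 2, 0 of 2 and 0 of 7 results. Depth is not given for ratio and RPM libraries. With shifts planted in simulated libraries, 45% of shifts of 1 and 87% of shifts of 2 were found for Sxl in Polr3E RNAi, and 0% and 2% for Dam alone in Polr3E RNAi.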

Other observations

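Tests on the scale of values, on sites with Polr3E and on the Sxl gene were chosen after the results were seen and are tests, not predictions. Sxl signal lay at single genes of several tissues, where 7967 of 17483 genes were bound in all. Neuronal and glial genes did not stand above other windows as lists. Next to the salivary glue genes Sgs4 and Sgs8, Sxl signal lay at rut (5.78 ± 0.47 at its low end) and Csp (4.91 ± 0.21), genes of neuronal function. It also lay at the blood-brain barrier gene moody (5.49 ± 0.90) and at Gs2, a glutamine synthetase gene (4.92 ± 1.79). In Polr3E RNAi moody was lower by -2.50 (SE 0.48, adjusted p = 0.00133), Gs2 by -3.31 (SE 0.66, adjusted p = 0.00171) and the larval serum protein gene Lsp1beta by -3.71 at its high end (SE 0.49, adjusted p = 0.000142).

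Changes in Polr3E RNAi also lay in both directions within single genes. Csp was lower at its low end by -3.45 (SE 0.33) and higher at its high end by 1.61 (SE 0.25). The dosage compensation RNA gene lncRNA:roX1 was higher at its low end by 0.59 (SE 0.20, adjusted p = 0.031). Among temporal genes chinmo was lower by -2.49 (SE 0.81, adjusted p = 0.0251), Eip93F by -2.24 (SE 0.21) and mamo by -3.35 (SE 0.43), while bru3 was higher by 1.12 (SE 0.35, adjusted p = 0.0207).

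The first pattern weighed was the lower Sxl signal at Sxl sites in Polr3E RNAi. For a narrower scale of the values, the difference was -1.10 (spread 0.09) after quantile normalization. Every compared group fell there by more than its spread, from -0.33 (C-terminal truncation, spread 0.13) to -2.19 (Tra, spread 0.62), with U1 at -1.08 (spread 0.67). The sites were chosen for a high Sxl signal, so any library with another order of fragments falls there. The test therefore cannot tell a narrower or weaker library from the knockdown. Raised Dam-alone signal under the RNAi was not seen in the libraries used here. Dam-alone signal at these sites was lower in Polr3E RNAi by -0.82 (spread 0.42) relative to all fragments. Over pairs of libraries it lay between -1.26 and -0.41. A lower control would raise a ratio, but the Dam-alone denominator of each ratio is not given. This explanation therefore stays open for the ratios themselves. At 159 sites with Polr3E the difference exceeded that at 1263 sites of like Sxl signal without it by -1.09, and by -0.89 after quantile normalization. The permutation p of the first was 0.0001, the smallest these permutations can give. Labels were permuted over sites, so this p does not measure the spread between libraries. Sxl libraries were themselves 0.54 higher at such sites and the RNAi libraries 0.55 lower. Smaller contrasts were found for U1 (-0.54, and -0.32 after quantile normalization), x16 (-0.45 and -0.19) and Tra (-0.23 and 0.25). The N-terminal truncation had 0.16 and 0.06, and the C-terminal truncation -0.08 and -0.002. Across gene windows, Polr3E libraries correlated at r = 0.39 to 0.72 with Sxl libraries and at 0.37 to 0.62 with the truncations. With the RNAi libraries they correlated at -0.02 to 0.14. A batch shared by Polr3E, Sxl and truncation libraries could therefore give such a contrast as well as the knockdown. As a hypothesis that these libraries cannot decide, part of Sxl binding may depend on Polr3E where Polr3E is found.

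For that pattern, a batch of libraries or a weaker fusion in the RNAi animals stays open and cannot be told apart from the knockdown. The RNAi libraries correlated with each other at r = 0.96 or more across gene windows, which are not independent replicates, at most at 0.60 with the pair of libraries of the Sxl group, at up to 0.64 with the male Sxl library and at up to 0.66 with the C-terminal truncation. The RNAi libraries also had less signal in the stretch of the Sxl gene (0.67 against 3.43 for Sxl), where construct reads may add to it, less on the mitochondrial genome (0.04 against 5.18), and 12.9% to 14.0% of their sites on X, against 19.4% and 19.9% in the Sxl libraries. These values go with a weaker fusion or another batch as well as with the knockdown. No library of Sxl with a control RNAi was used here.

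The second pattern was the lower Dam-alone signal at tRNA genes in both RNAi groups. Among 10000 random lists matched for Dam-alone signal, the tRNA median lay at percentile 0 in both RNAi groups. In Polr3E RNAi it was -0.34, against a matched median of 0.10 and a lowest value of -0.16. In Polr3A RNAi it was -0.84, against -0.27 and -0.62. Within these libraries this argued against a general fall of windows with a high Dam-alone signal. The lists were drawn window by window from the same libraries, so the percentile leaves out likeness among tRNA windows and the spread between libraries. A single library as the source was argued against, since over all pairs of libraries the tRNA median relative to all windows lay under 0. Its size depended on the control, which all pairs share. It lay between -0.68 and -0.61 against the first Dam-alone library without RNAi, and between -0.39 and -0.27 against the second. These controls correlated at r = 0.87 across windows, and the second at 0.90 with the first Polr3E RNAi library. The fall was not confined to genes of RNA polymerase III. In Polr3E RNAi the median relative to all windows was -0.76 for neuroblast genes (-1.03 to -0.54 over pairs of libraries) and -1.01 for Pol II snRNA genes (-1.25 to -0.66), against -0.46 for tRNA genes. In Polr3A RNAi it was -0.82 for temporal and mushroom body neuron genes (-1.01 to -0.29) against -0.59 for tRNA genes, and Pol II snRNA genes did not pass there (adjusted p = 0.246). The tRNA calls had an adjusted p = 0.944 with an estimated correlation, and a batch difference between RNAi and other Dam-alone libraries was not tested.

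The third pattern was the high signal in a stretch of the Sxl gene in Sxl fusion libraries. Reads from the fusion construct may be a part of it, since N-terminal minus C-terminal truncation was 3.08 (spread 0.68) at its high end fragment and -1.99 (spread 1.51) at its low end fragment. Sxl had 6.12 and 2.45 at these fragments, the N-terminal truncation 4.21 and 0.36, and the C-terminal truncation 1.13 and 2.35. Binding of Sxl to its own gene stays open and cannot be told apart from such reads, since of the fragments beside the stretch the lower had 1.07, below the bound of 1.71 set for it, and the other had 2.18. In Polr3E RNAi the stretch was low as well, at 0.67, so its share of the construct signal is open too.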
